A study of Mus musculus with 4 samples.

How the data were processed

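Total RNA of 4 RAW264.7 cultures was labelled with Cy3 and hybridised to Agilent mouse expression arrays of design 074809, per the labels and the file headers. The groups were wild type untreated, wild type with LPS, knockout untreated and knockout with LPS, with 1 array each. All 4 arrays lay on 1 slide with 1 scan time, and each had its own position on the slide, so position cannot be separated from the group. The dose and duration of LPS and the way the knockout was made are not given in the sources used here.

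The scanner files hold spot intensity on a linear scale, extracted by Agilent Feature Extraction 10.7.1.1, per the file headers, while the authors' processing notes name version 9.5.1.1. The processed signal is background subtracted and detrended within an array and low spots are replaced by a surrogate value, per the file headers, with no normalization between arrays. The deposited flags are a unit of the type other, 0 or 1 for each spot, and give whether it was well above background, saturated or an outlier. The deposited series table holds intensity on a linear scale, and its values match quantile normalized probe means: between 56544 and 56578 of 56605 probes on an array lay within 0.01 log2 of a quantile normalization of the processed signals. That table was used as an alternative.

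The main values were log2 of the processed signal minus each array's 75th percentile over non-control probes, which before scaling was between 463 and 567. Control spots and outlier spots were left out, and the spots of a probe were averaged. Of the probes, 32994 (58.3%) were named through their RefSeq accession in a table of the GRCm38.p6 annotation, used for names only, 520 through an older symbol, and 23091 kept the name in the file. Probe coordinates are those of the files, in mm9. Each gene was represented by 1 probe, preferring probes with a value on all 4 arrays, then those above background on at least 1 array, then the probe with the highest mean signal. The preference for a value on all 4 arrays was decided after the data were examined. Other probes of a gene were used to check the direction of the genes named.

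A gene counted as higher or lower when its difference was 1 or more in size on the log2 scale on 2 arrays above background. When it was above background on 1 array, the dim array was set to the higher of its own signal and the lowest signal well above background on that array, and the call needed a bound of 2-fold. The difference of the LPS responses used genes above background on all 4 arrays. No p-value was computed for comparisons of single arrays. The 39 gene lists were fixed before the data were examined, and 651 of their 656 genes were on the array. List members above background on at least 1 of the arrays compared entered the medians with their measured value, and medians with bounded members at their bound are given where they differ. For the difference of the LPS responses, counts, medians and percentiles of lists are given over members above background on all 4 arrays, a choice made after the data were examined. Percentiles came from 10000 random lists of the same size drawn within 20 bins of mean expression, for lists with at least 3 measured genes.

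The rule for named genes was also fixed before the data were examined. It takes Hsd17b4 and a fixed set of key genes, the 10 largest positive and 10 largest negative differences of each comparison among genes with a symbol measured on every array compared that also differ by at least 2-fold in the same direction under the normexp and quantile alternatives, the 5 largest bounds in each direction, and up to 4 members of each list with the largest difference. Some genes that met the rule are not reported here. An additive fit on all 4 arrays used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, genes above background on at least 2 arrays). Other steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9. Alternatives were normexp background correction (offset 50), quantile normalization, centring on 7 spike-in probes, median centring, a stricter filter and no filter on dim probes, the mean of a gene's probes, 1.5-fold and 4-fold thresholds, the deposited series table, and for the additive fit a trended prior and a stricter filter.

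The call rule was tested on simulated data with the spot noise of these arrays. The additive fit was tested on simulated data with the same noise for every gene, an SD of 0.147 from the fit's prior. For the LPS response of wild type, among 37008 genes of which 200 were changed, the call rule recovered 92% of changes of 1.5 and 91% of changes of 3 on the log2 scale, and called 0 unchanged genes. For the LPS term of the additive fit, among 17365 genes of which 200 were changed, 100% were recovered at sizes 2 and 4, and 8 unchanged genes were called. For lists, the measured untreated genotype differences were used without simulation. Of 100 random lists of 20 genes, 9% lay outside percentiles 2.5 to 97.5, above the nominal share. Random lists do not show how far genes of a fixed list vary together between cultures. The call-rule simulation carries noise within an array and no difference between cultures. The additive simulation leaves out that noise can differ between genes.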

Results

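Messenger RNA levels were measured on 4 one-colour arrays hybridised with Cy3-labelled RNA from RAW264.7, a mouse macrophage cell line. The groups were wild-type cells and cells labelled as lacking Mfp2, each without and with lipopolysaccharide (LPS), the bacterial cell wall component that activates macrophages through Toll-like receptor 4. Mfp2 is the peroxisomal multifunctional protein encoded by Hsd17b4, an enzyme of peroxisomal fatty acid beta-oxidation, and these cells are called knockout here. Each group had 1 array, so no difference has a replicate check, and no p-value is given for a comparison of 2 arrays. The number of arrays limits the precision. Between 47.4% and 49.7% of the non-control spots of an array were well above background, and 0 non-control spots were saturated. Of 37008 genes and transcripts, 19475 were above background on at least 1 array and 15516 on all 4. The spread between replicate spots of a probe, a measure of error within an array, gave a difference of 2 arrays a technical SD between 0.0572 and 0.107 on the log2 scale. Differences are log2 values unless a fold is named, and a gene counted as higher or lower when it differed by at least 2-fold. Where a gene was above background on 1 of the arrays compared, the dim array was set to at least the lowest signal well above background on it, and the fold is written as "at least". A gene list is described by the median difference of its measured genes, and by the percentile of that median among 10000 random lists of the same size and mean expression on the same arrays. The percentile describes these arrays and is no replicate check, since genes of a list can vary together between cultures.

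Hsd17b4 transcript was lower in the cells labelled knockout in both conditions and was not lost. Its probe (A_51_P445662, chromosome 18, 50355686 to 50355745 in the mm9 coordinates of the files, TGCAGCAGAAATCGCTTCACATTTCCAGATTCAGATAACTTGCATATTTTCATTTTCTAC) was well above background on all 4 arrays. The signal on the linear scale was 4482 in untreated wild type, 2915 in wild type with LPS, 2545 in untreated knockout and 1217 in knockout with LPS. After scaling, the difference between knockout and wild type was -0.86 without LPS and -1.17 with LPS, or 55.0% and 44.4% of the wild-type signal, against technical SDs of 0.0770 and 0.103. These SDs do not cover differences between cultures. Among the genes of each comparison the 2 differences lay at percentiles 2.71 and 2.07, so other genes were lower still. The difference with LPS passed the 2-fold rule and the difference without LPS did not. Between LPS and untreated cells the transcript differed by -0.47 in wild type and by -0.78 in knockout. The labels do not say which part of the gene was disrupted, so this single probe does not check whether the edited part or the protein is missing.

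**Figure D1:**
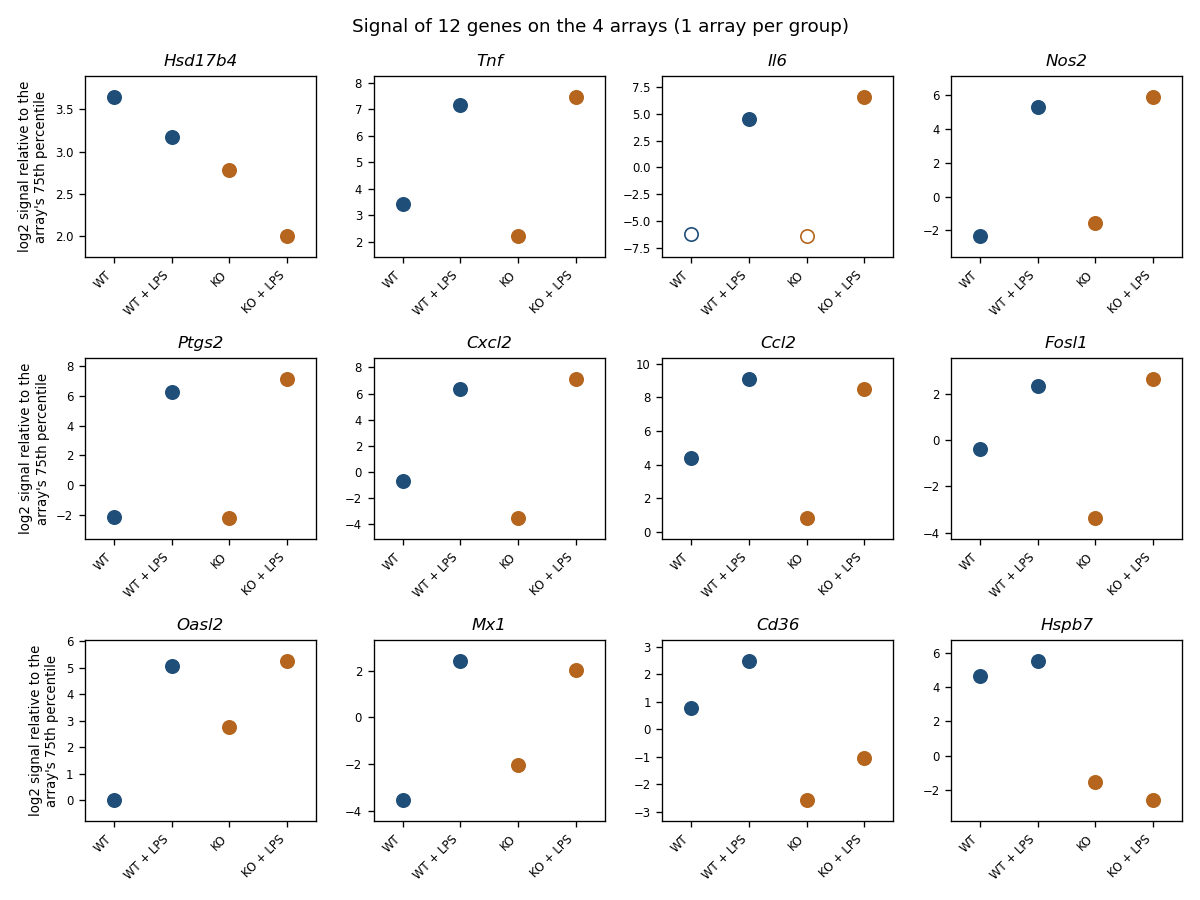
Signal of 12 genes on each of the 4 arrays, as log2 signal relative to the array's 75th percentile (y axes differ in range), with wild type in blue and knockout in brown and 1 point per array. Open circles are probes not well above background, as for Il6 without LPS, and Hsd17b4 was -0.86 (untreated) and -1.17 (with LPS) from wild type on this scale.

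The first comparison asked how wild-type cells responded to LPS. Lcn2, which encodes the iron-scavenging lipocalin 2, was 509-fold higher with LPS, Hdc, the enzyme that makes histamine, 380.3-fold, Ptgs2, the inducible cyclooxygenase, 346-fold, and Nos2, the inducible nitric oxide synthase, 199.8-fold. The chemokine genes Ccl7, Ccl5 and Cxcl2 were 201-fold, 181-fold and 128-fold higher, and Saa3, an acute phase gene, 180.3-fold. Several cytokine genes were below background without LPS: Il1b was at least 3658-fold higher, Csf3 at least 1138-fold, Il1a at least 517-fold and Il6 at least 359-fold. Ranbp3l (-4.42), the linker histone gene H1f5 (-3.97), Neurl1b (-3.73), Ankle1 (-3.70) and Hpgd (-3.67), which encodes the enzyme that inactivates prostaglandins, were the largest measured decreases by the rule for named genes. In all, 1768 genes were higher and 1562 lower among 18200 compared, and 438 and 319 of these calls rest on a bound.

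Genes of inflammation and of the interferon response were higher as groups. Of 16 measured inflammatory cytokines 15 were higher and 0 lower (median 4.15, or 3.90 with bounded members at their bound), among them Tnf with 3.74 and Ifnb1, the gene of interferon beta, with 3.43. Of 16 chemokines, which attract leukocytes, 13 were higher and 0 lower (median 4.17, or 3.27 with bounds), with Cxcl10 at 3.64. In the NF-kB pathway and its feedback 20 of 24 genes were higher and 0 lower (median 1.60), with Socs3 at 5.52 and Nfkbiz at 4.29. Of 41 interferon-stimulated genes 39 were higher and 0 lower (median 3.30), including Gbp3 at 6.47, Ifit3 at 6.33, Ifit1 at 5.30 and Irf7 at 3.33. Nitric oxide and oxidant production had 8 of 14 genes higher and 0 lower (median 1.94, or 1.64 with bounds), with Acod1, which makes itaconate, at 6.58 and Ass1 at 4.05. In antigen presentation and costimulation 8 of 17 genes were higher and 0 lower (median 1.02, or 0.99 with bounds), led by Cd40 with 6.36 and Tap1 with 2.72. The medians of these 6 lists all lay at percentile 100 of their matched lists, as did the 2 lists that follow. The unfolded protein and integrated stress response list had 10 of 19 genes higher and 0 lower (median 1.09), with Trib3 at 3.88, Chac1 at 3.57 and Ddit3 at 2.79. Proteases and matrix genes had 7 of 12 higher and 1 lower (median 3.07, or 1.89 with bounds), among them Timp1 with 4.98 and Mmp9 with 4.45. The NRF2 targets, genes of the oxidant defence, had 4 of 13 higher and 0 lower (median 0.71, percentile 99.96), with Slc7a11 at 3.61 and Hmox1 at 2.37. PPAR targets and lipid droplet genes went both ways, with 5 of 15 higher and 2 lower (median 0.61, percentile 99.96), such as Fabp4 at 4.24 and Angptl4 at -2.63. The lysosome list had 1 of 21 genes higher and 0 lower (median 0.35, percentile 99.63), and the heat shock proteins 1 of 10 higher and 0 lower (median 0.43, percentile 98.57).

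Cell cycle genes and several lipid enzymes were lower with LPS in wild-type cells. Of 29 cell cycle genes 21 were lower and 0 higher (median -1.71, percentile 0), including Kif11 at -2.97, Ccna2 at -2.85 and Mki67 at -2.47. In prostaglandin and leukotriene synthesis 5 of 16 genes were lower and 1 higher (median -0.57, percentile 0.09, but a median of 0.0016 with no filter on dim probes), with Alox5 at -2.26 and Ptgs1 at -2.05 against Ptgs2 at 8.43. Peroxisomal fatty acid oxidation had 2 of 18 genes lower and 0 higher (median -0.35, percentile 0.92), namely Hacl1 at -1.49 and Acox3 at -1.36, for which another probe gave 0.20. Ech1 was -0.88 and Scp2 -0.24, below 2-fold, and Ehhadh and Abcd2 were below background. Mitochondrial fatty acid oxidation had 2 of 16 genes lower and 0 higher (median -0.35, percentile 1.13), Hadh at -1.22 and Cpt1a at -1.17, and the respiratory chain 0 lower and 0 higher of 24 (median -0.20, percentile 0.01). With normexp background correction the counts fell to 1155 higher and 917 lower. With centring on spike-in probes, which moved the median of all measured genes from 0.0176 to -0.174, they were 1360 higher and 2159 lower.

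The second comparison asked how knockout cells responded to LPS. Cxcl2 was 1591-fold higher with LPS, Lcn2 1239.7-fold, Ptgs2 673-fold, Saa3 439.8-fold and the formyl peptide receptor gene Fpr2 233-fold. Below background without LPS were Il1b, at least 3806-fold higher, Csf3, at least 2129.6-fold, and Il6, at least 1733-fold. Tnf was 5.24, Ifnb1 4.93, Nos2 7.44 and Cd40 7.40 higher. Hpgd (-6.26), Ranbp3l (-5.47), Scel (-5.30) and Mettl7a2 (-4.77) were the largest measured decreases by the same rule. A total of 2027 genes were higher and 2294 lower among 18388 compared, 410 and 505 of them by a bound.

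The inflammatory and interferon groups were higher in knockout cells too. Higher were 15 of 17 inflammatory cytokines (median 5.52, or 5.24 with bounds), 14 of 17 chemokines (median 5.50, or 3.73 with bounds), 22 of 24 NF-kB genes (median 2.18) and 36 of 41 interferon-stimulated genes (median 2.18), each at percentile 100, and of these lists 1 chemokine gene was lower. Immediate early genes, which are switched on early after a stimulus, were higher in 9 of 15 cases and lower in 2 (median 1.83, percentile 100), with Fosl1 at 6.01, Ier3 at 4.53 and Klf4 at -2.63. In wild type 5 of these 15 had been higher and 4 lower (median 0.48, percentile 99.8), with Myc at 4.49 and Egr3 at -2.90. The stress response list had 12 of 19 genes higher and 0 lower (median 1.65, percentile 100), with Trib3 at 4.92 and Ddit3 at 4.09. Proteases and matrix genes had 8 of 12 higher and 2 lower (median 3.86, or 2.18 with bounds, percentile 100), including Mmp9 at 6.29 and Plaur at 5.53. The macrophage scavenger receptor gene Msr1 was 5.75 higher. Alternatively activated macrophage markers had 3 of 5 higher and 1 lower (median 1.46, percentile 99.62), with Tgm2 at 2.62. Of 29 cell cycle genes 21 were lower and 0 higher (median -1.26, percentile 0), including E2f1 at -2.47 and Ccna2 at -2.46.

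Several lipid gene lists lay below 0 in the LPS response of knockout cells. Peroxisomal fatty acid oxidation had 6 of 18 genes lower and 0 higher (median -0.74, percentile 0.03), among them Hacl1 (-1.97) and Acaa1b (-1.45). Mitochondrial fatty acid oxidation had 3 of 16 lower and 0 higher (median -0.63, percentile 0.04), with Cpt1a, the entry enzyme of that pathway, at -2.29. In fatty acid synthesis, elongation and desaturation 5 of 20 were lower and 3 higher (median -0.53, percentile 0.12), such as the desaturase gene Scd1 at -1.97 and Elovl3 at 2.05. Cholesterol synthesis and uptake had 3 of 23 lower and 1 higher (median -0.32, percentile 2.1), with Tm7sf2 at -1.68. The plasmalogen and peroxisomal antioxidant list had 2 of 7 genes higher, Prdx5 (1.98) and Tmem189 (1.06), and 0 lower (median -0.18, percentile 21.36). Of the other 17-beta-hydroxysteroid dehydrogenases 1 of 7 was higher, Hsd17b13 by 2.79-fold, though it was -0.64 with the mean of its probes, and 0 lower (median -0.60, or -0.52 with bounds, percentile 8.41). With normexp background correction 1345 genes were lower. With spike-in centring, which moved the median of all measured genes from 0.0354 to -0.184, 1501 were higher and 3130 lower.

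Most of the response was shared by the genotypes. Lcn2, Ptgs2, Nos2, Hdc, Saa3 and Cxcl2 were among the 10 largest measured increases in both, and Ranbp3l, Hpgd, H1f5, Neurl1b and Cnnm1 among the 10 largest measured decreases. Among 17113 genes compared in both, 1271 were higher in both against 176 for independent lists, and 1103 were lower in both against 171. The genes higher in both were 80.0% of the wild-type and 66.9% of the knockout increases among these genes. Those lower in both were 78.8% of the wild-type and 52.6% of the knockout decreases. Another 9 were higher in wild type and lower in knockout, and 9 were lower in wild type and higher in knockout. Across 15516 genes above background on all 4 arrays, the 2 responses, which share no array, had a Pearson r of 0.886 and a Spearman rho of 0.861, as a description, since genes are not independent replicates. In a limma fit with genotype and LPS as additive terms, 3919 of 17365 genes changed with LPS at a Benjamini-Hochberg adjusted p under 0.05, 1954 higher and 1965 lower. That fit has 1 residual degree of freedom per gene and takes any difference between the responses as noise, and it gave 6440 genes with a trended prior and 6115 with normexp background correction, and 1499 higher and 2942 lower with spike-in centring.

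**Figure D2:**
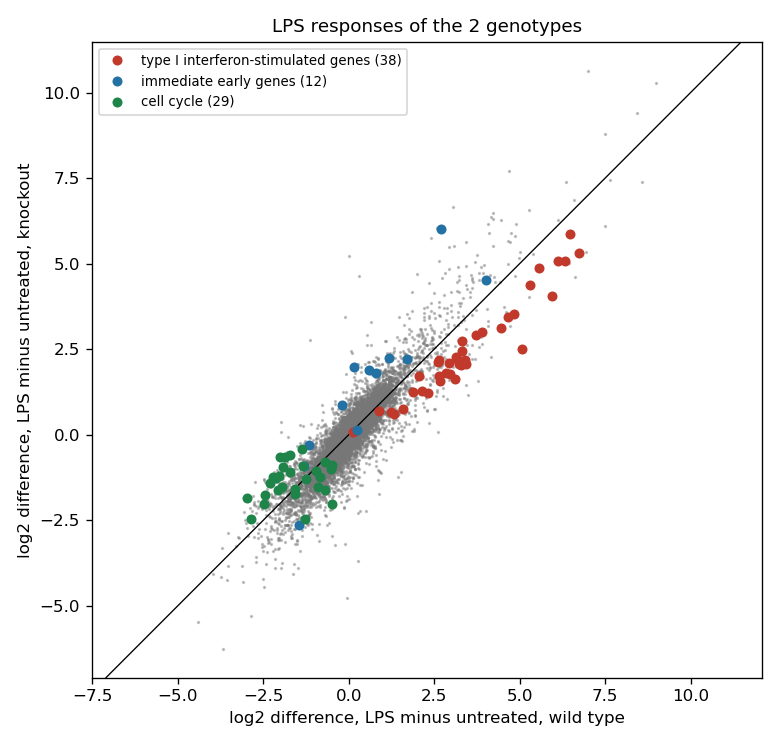
Log2 difference between LPS and untreated cells in wild type (x axis) and knockout (y axis), 1 point per gene for 10942 genes with a symbol above background on all 4 arrays, with 3 gene lists coloured and the line of equal response. The 38 interferon-stimulated genes drawn lie below the line, the 12 immediate early genes had a median difference between the responses of 0.93, and the 29 cell cycle genes lie below 0 on both axes.

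The third comparison asked how untreated knockout cells differed from untreated wild-type cells. Ly6c2, a surface antigen gene of the Ly6 family, was 615-fold lower in knockout and its neighbour Ly6c1 at least 1617-fold lower; whether each probe reads its own gene alone was not tested. Hspb7, a small heat shock protein gene, was 73.9-fold lower, the membrane protein gene Emp2 33.5-fold, the RNA-binding protein gene Igf2bp3 30.6-fold, Ndst1 28.5-fold and Msr1 18.5-fold, and Tbx21, the T-bet transcription factor gene, at least 152-fold. Higher in knockout were Cbfa2t3 (18.3-fold), Klhl30 (16.3-fold), Zfp979 (8.66-fold), Serpinf1 (7.96-fold) and the interferon-stimulated gene Oasl2 (6.81-fold). In total 567 genes were higher and 717 lower among 18400 compared, 251 and 365 of them by a bound.

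Untreated knockout cells had less transcript of immediate early and chemokine genes and more of interferon-stimulated genes. All 15 measured immediate early genes were below wild type, 8 of them by at least 2-fold and 0 higher (median -1.03, percentile 0), including Fosl1, 8.03-fold lower, Fos at -1.82 and Egr3 at -1.60. Of 11 chemokines 6 were lower and 1 higher (median -1.06, percentile 0), with Ccl2 at -3.57, Cxcl2 at -2.87, Ccl4 at -2.56 and Ccl5 at 1.54, and this median was -0.42 with normexp background correction. The NF-kB list had 4 of 24 genes lower and 1 higher (median -0.49, percentile 0), among them Traf1 (-1.89), Irak3 (-1.83) and Nfkbiz (1.03). Inflammatory cytokines had 3 of 10 lower and 1 higher (median 0.19, percentile 95.26), with Tnf 2.30-fold lower, Il1rn at -2.21 and Il15 at 1.09. Proteases and matrix genes had 5 of 9 lower and 0 higher (median -1.03, percentile 0), with Mmp9 at -2.69 and Plaur at -2.53. Of 40 interferon-stimulated genes 7 were higher and 0 lower (median 0.78, or 0.74 with bounds, percentile 100), with Mx1 at 1.51, Ifi44 at 1.40 and Zbp1 at 1.29. Antigen presentation had 3 of 17 genes higher and 1 lower (median 0.48, percentile 100), with Cd86 at least 4.70-fold higher and H2-Eb1 at -1.14. Prostaglandin and leukotriene synthesis had 4 of 15 higher and 0 lower (median 0.19, percentile 96.87), with Hpgd at 1.93 and Alox5 at 1.32. Osteoclast markers had 3 of 12 higher and 3 lower (median -0.41, percentile 0), with Itgb3 at 2.46 and Ocstamp at -2.72.

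No gene of the 2 peroxisome lists passed the 2-fold rule without LPS. Of 18 peroxisomal fatty acid oxidation genes 0 were higher and 0 lower (median 0.19, percentile 99.12), and of 16 peroxisome biogenesis genes 0 were higher and 0 lower (median 0.17, percentile 95.17), with Hacl1 at 0.77, Scp2 at 0.19 and Pex10 at 0.42. Cholesterol synthesis and uptake had 0 of 23 genes higher and 0 lower (median 0.24, percentile 99.99). Single lipid genes differed by more: the fatty acid receptor gene Cd36 was -3.35, Pparg, the nuclear receptor of fat storage, -2.43 and Fabp4 -1.33, the 3 lower genes of 15 PPAR targets and lipid droplet genes, of which 0 were higher. LXR targets and lipid efflux had 1 of 10 higher, Apoc2 (2.40), and 1 lower, Pltp (-2.19), with a median of 0.35 (percentile 99.9). Phospholipid acyl remodelling had 1 of 14 lower, Agpat4 (-1.31), and 0 higher (median 0.06, percentile 46.82). Toll-like receptor components had 0 of 18 higher and 0 lower (median 0.20, percentile 99.22), with Tlr4 at 0.34. Ribosomal proteins had 0 of 35 higher and 0 lower (median 0.09, percentile 88.72). The probes of Rps24 (-4.21) and Bin1 (-4.24) ranked among the 10 largest decreases, but other probes of these genes reached 0.44 and 0.35. With normexp background correction 216 genes were higher and 309 lower, and with only genes above background on both arrays 316 and 352.

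The fourth comparison asked how knockout differed from wild type when both had received LPS. Hspb7 was 275-fold lower, Emp2 30.0-fold, Igf2bp3 26.9-fold and Ndst1 18.5-fold, Cd36 was -3.54, Ly6c2 was at least 1331-fold lower, and the interleukin-7 receptor gene Il7r was -4.09. Higher in knockout were Nyap1 (8.85-fold), Zfp979 (8.16-fold), Trem3 (7.18-fold), Scarf1 (5.77-fold), Stc2 (5.65-fold) and the cytokine genes Tslp (5.13-fold), Lta (5.09-fold) and Il6 (4.22-fold). There were 329 genes higher and 779 lower among 17727 compared, 120 and 323 of them by a bound.

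With LPS the immediate early, chemokine and interferon lists lay nearer to wild type, and other lists differed. Immediate early genes had 3 of 15 lower and 0 higher (median -0.05, percentile 13.725), and chemokines 2 of 17 lower and 1 higher (percentile 30.985), with Ccl7 at -1.80 and Cx3cl1 at 1.89. Interferon-stimulated genes had 1 of 41 lower, Ifi205 (-2.10), and 0 higher (median -0.18, percentile 0). Inflammatory cytokines had 5 of 17 higher and 1 lower (median 0.70, percentile 100), among them Il6 (2.08), Ifnb1 (1.74) and Tnfsf15 (-2.07). The stress response list had 5 of 19 higher and 0 lower (median 0.62, percentile 100), including Trib3 (1.43) and Ddit3 (1.25). Cell cycle genes had 4 of 29 higher and 1 lower (median 0.51, percentile 100), including Bub1b (1.35), Cenpe (1.24) and Ccne1 (-1.03). NRF2 targets had 0 of 13 higher and 0 lower (median 0.29, percentile 99.96), glycolysis and hypoxia genes 2 of 20 higher and 0 lower (median 0.22, percentile 99.86), with Bnip3 at 1.30, and p53 targets 3 of 14 higher and 0 lower (median 0.20, percentile 93.65), with Gdf15 at 1.60. Osteoclast markers had 4 of 12 lower and 1 higher (median -0.63, percentile 0), among them Ocstamp (-3.26) and Dcstamp (-1.52), 2 genes of cell fusion. Proteases and matrix genes had 3 of 12 lower and 2 higher (median -0.84, or -0.78 with bounds, percentile 0), with Serpinb2 at -3.32 and Mmp13 at 1.58. Peroxisomal fatty acid oxidation had 1 of 18 genes lower and 0 higher (median -0.10, percentile 1.23), and Scd1 was -1.14.

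Part of the genotype difference was present in both conditions. Higher in both were 94 genes, Zfp979 and Nyap1 among them, against 4.45 for independent lists, and 214, including Hspb7, Emp2, Igf2bp3, Ndst1 and Cd36, were lower in both against 16.9. The sources used here do not say whether the knockout cells came from a single clone, and a difference between clones would be part of both genotype differences. The genotype differences without and with LPS, which share no array, had a Pearson r of 0.446 and a Spearman rho of 0.293 across 15516 genes, which are not independent replicates. In the additive limma fit, 0 genes changed with genotype at a Benjamini-Hochberg adjusted p under 0.05, 1708 had an unadjusted p under 0.05, and the adjusted count was 86 with a trended prior, 59 with normexp, 11 with genes above background on all 4 arrays and 0 with quantile normalization, spike-in centring or median centring. With normexp background correction 126 genes were higher and 311 lower with LPS, and with only genes above background on both arrays 209 and 456.

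**Figure D3:**
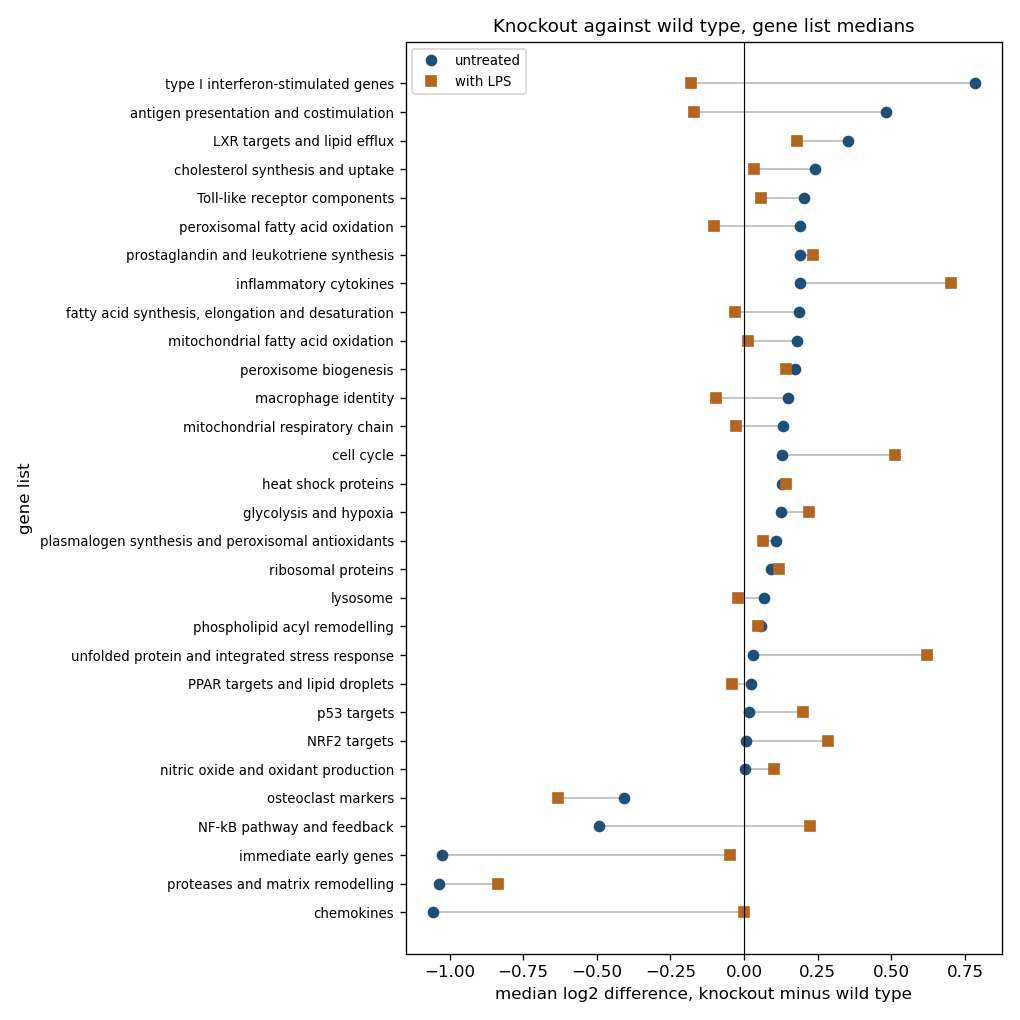
Median log2 difference between knockout and wild type over the measured genes of 30 gene lists with at least 7 measured genes (x axis), without LPS (circles) and with LPS (squares), joined by a grey line for each list. Immediate early genes lay at -1.03 without and -0.05 with LPS, interferon-stimulated genes at 0.78 and -0.18, and chemokines at -1.06 without LPS (-0.42 with normexp background correction).

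The last comparison asked whether the LPS response differed between knockout and wild type, as the difference of the 2 log2 responses. The response was more positive in knockout for Id3 (3.90), an inhibitor of DNA binding, Cxcl2 (3.63), Plk2 (3.46), Msr1 (3.35) and Fosl1 (3.32), and by 7.99-fold for Ccl2 and 2.83-fold for Tnf. It was more negative for Mettl7a2 (-4.72), Rabif (-2.72), Ccdc80 (-2.67), Hpgd (-2.59) and Oasl2 (-2.57), which for Hpgd was a larger decrease and for Oasl2 a smaller increase. Of 15516 genes above background on all 4 arrays, 262 had a response more positive by at least 2-fold in knockout and 452 one more negative by at least 2-fold. The value equals the genotype difference with LPS minus that without. A gene that was low in untreated knockout cells and near wild type with LPS therefore has a more positive response by arithmetic. Likewise, a gene that was high in untreated knockout cells and near wild type with LPS has a more negative one.

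All 38 interferon-stimulated genes above background on all 4 arrays had a smaller response in knockout, 17 of them by at least 2-fold (median -0.94, percentile 0), including Mx1 (-1.89), Zbp1 (-1.42) and Oasl2. Against wild type, the median of this list over its measured genes was 0.78 without LPS and -0.18 with LPS. The smaller response thus came mostly from the higher untreated level by arithmetic. Immediate early genes had 5 of 12 responses more positive and 1 more negative (median 0.93, percentile 100), with Nr4a1 at 1.81 and Klf4 at -1.18. Chemokines had 4 of 10 more positive and 1 more negative (median 0.56, percentile 100), with Ccl4 at 2.55 and Ccl5 at -1.40, and NF-kB genes 6 of 24 more positive and 0 more negative (median 0.59, percentile 100), among them Irak3 (2.71) and Traf1 (1.92). Inflammatory cytokines had 4 of 9 more positive and 1 more negative (median 0.64, percentile 100), with Il1rn at 2.08 and Il15 at -1.75. The stress response list had 6 of 19 more positive and 0 more negative (median 0.51, percentile 100), with Ddit3 at 1.30. Cell cycle genes had 4 of 29 more positive, so less of a decrease, and 2 more negative (median 0.43, percentile 100), with Cenpe at 1.37 and Ccne1 at -1.55. Antigen presentation had 3 of 14 more negative and 1 more positive (median -0.38, percentile 0), with Tap1 at -1.23 and Cd40 at 1.04. Peroxisomal fatty acid oxidation had 2 of 18 more negative and 0 more positive (median -0.32, percentile 0), with Acaa1a at -1.02. The probes of Bin1 (4.34), Rps24 (3.56), Ano10 (-3.98), Fcgr3 (-3.10) and Ccdc77 (-2.83) also ranked among the 10 largest in size in either direction, but another probe of each pointed the other way, and Rpl17-ps8 (5.23) had 1 probe. With normexp background correction 144 responses were more positive and 231 more negative.

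A few macrophage identity genes differed between genotypes, and few markers of lymphoid, stromal and other myeloid cells were measured. Macrophage identity genes had 3 of 17 higher and 1 lower in untreated knockout cells (median 0.15, percentile 95.495), with Fcgr1 at 1.61, Mertk at least 6.70-fold higher and Msr1 18.5-fold lower, and 1 of 16 higher and 2 lower with LPS (median -0.09, percentile 1.39). In the wild-type LPS response, T cell markers had 2 of 4 measured genes higher and 0 lower (median 0.98, or 0.62 with bounds, percentile 97.36), with the T cell kinase gene Lck at 1.72, and 1.85 in knockout. B cell markers had 1 of 4 higher there, Pax5 by at least 2.20-fold, and in the knockout response Cd79b was at least 8.20-fold higher. In knockout against wild type, Ebf1 was at least 2.27-fold lower without LPS, and with LPS Cd79b was 5.35-fold higher and Pax5 at least 2.12-fold lower. Both measured fibroblast markers were higher with LPS in wild type, Fap by at least 4.14-fold and Dcn by at least 3.28-fold, as was the 1 measured epithelial marker, Cdh1, by at least 2.08-fold. A gene above background on 1 of the 2 arrays compared, as for each "at least" fold here, can be called in only 1 direction. The direction is set by which array was above background. For Fap, Dcn and Cdh1 in wild type that was the array with LPS. With LPS, Fap was at least 3.98-fold lower in knockout than in wild type, and Cdh1 at least 2-fold lower. The endothelial marker Vwf was at least 2.97-fold lower in knockout with LPS, 1 of 3 measured in its list, and at least 2.07-fold lower with LPS in the knockout response. Of the neutrophil markers Camp was at least 2.25-fold higher with LPS in knockout, 1 of 3 measured, and of the dendritic cell markers Itgax was 2.19 higher with LPS in wild type, 1 of 2 measured, and Siglech 1.47 in knockout, 1 of 3. Without LPS, Itgax was 1.32 and Siglech -1.07 in knockout against wild type. The T cell, B cell, fibroblast, epithelial, endothelial, neutrophil and dendritic cell lists had at most 4 measured genes in any comparison.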

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

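The tests of the pattern weighed here were chosen only after the result was seen. Some genes and lists went one way in 1 genotype or condition and the other way in the other, which drew attention, and these differences were not tested because each group had 1 array. In the LPS response, Id3, which encodes an inhibitor of DNA binding, was -1.13 in wild type and 2.77 in knockout. Ccdc80 was 1.43 in wild type and -1.23 in knockout, Prkag3 was 1.53 in wild type and -1.09 in knockout, and Arhgap31 was 1.38 in wild type and -5.40 in knockout, a bound in knockout. In the genotype difference, Ccdc80 was 1.05 without LPS and -1.62 with LPS, and Lta, as a bound without LPS, -1.38 without LPS and 2.35 with LPS. Among list medians, the NF-kB list was -0.49 without LPS and 0.23 with LPS, interferon-stimulated genes 0.78 and -0.18, antigen presentation 0.48 and -0.17, peroxisomal fatty acid oxidation 0.19 and -0.10, and the respiratory chain 0.13 and -0.03.

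Untreated knockout cells had lower immediate early and chemokine genes and higher interferon-stimulated genes than untreated wild type. The choice among the scalings tried is argued against as the whole cause, since the immediate early median was between -1.06 and -1.08 under quantile normalization, spike-in centring and median centring. These scalings moved the median of all measured genes only from 0.050 to between 0.009 and 0.018, so they could move the lists little. With normexp, a background correction, the immediate early median was -0.829 and the chemokine median -0.42. Signal near background is argued against by the 10 immediate early members above the 75th percentile on all 4 arrays, of which 10 lay below wild type, with a median of -0.966. A difference between single cultures other than genotype, such as clone, density or handling, cannot be told apart from genotype, since there was 1 untreated array per genotype. An effect of the knockout on inflammatory genes at rest stays open as a hypothesis and was not tested.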

How the results depend on the processing

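Slide as a block was not run because all arrays lay on 1 slide. Counts are compared within 1.5 times, a tolerance set after the data were examined, and the cause was not tested unless stated. With normexp background correction the counts were 1155 higher and 917 lower for the wild-type LPS response, 1345 lower for the knockout response, 216 higher and 309 lower for genotype without LPS, 126 and 311 with LPS, and 144 more positive and 231 more negative responses in knockout. A filter keeping only genes above background on every array compared gave, with fewer genes by construction, 316 and 352 for genotype without LPS and 209 and 456 with LPS. With no filter on dim probes, which adds genes near background, the counts were 3223 and 3026 (wild-type response), 3475 and 3963 (knockout response), 1875 and 2232 (genotype without LPS), 1384 and 2210 (with LPS) and 2727 and 3060 (difference of responses), and the correlation of the responses was 0.574. By construction, the 1.5-fold threshold gave, in that order, 3219 and 3186, 3720 and 4104, 1347 and 1371, 1107 and 1705, 887 and 1280, and the 4-fold threshold 608 and 274, 640 and 485, 100 and 212, 37 and 177, 39 and 35. Hsd17b4 was -0.95 without LPS with quantile normalization, -0.95 with the series table, and -1.04 with LPS under normexp. The additive limma fit gave 6440 LPS and 86 genotype genes with a trended prior, 6115 and 59 with normexp, and 11 genotype genes among genes above background on all 4 arrays. The all-gene median moved by over 0.1 with spike-in centring alone, for the LPS responses.

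Reversed values were few. The median of alternatively activated macrophage markers in the difference of responses was 0.18 with only genes above background on every array, against -0.91 over all measured members, the set used for list medians in this part. Prostaglandin and leukotriene synthesis was 0.0016 in the wild-type response with no filter and 0.0543 in the difference of responses with the mean of a gene's probes. Dendritic cell markers were 0.44 in the difference of responses with no filter, and Hsd17b13 was -0.64 in the knockout response with the mean of its probes. In all, 4 of 1539 list medians and 1 of 6296 gene values over these settings changed sign after being called. A further 363 and 1258 moved by more than the technical SD, and 1172 and 5037 moved by less. Values near 0 could cross it without being counted as reversed. The stricter filter and no filter leave a gene's value unchanged, so all 787 gene values under each stayed the same by construction. The genes with the largest measured differences were chosen to keep their direction under normexp and quantile normalization. The series table matches quantile normalized values. Signal over background limits the weakest genes, since under 50% of spots were well above it.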

Other observations

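The test of chromosome 13 copy number by signal level was fixed before its result was seen, and the other tests in this part were chosen only after theirs. Histone genes, a family chosen after the values were seen, were lower with LPS in both genotypes. Of 45 genes with H1, H2A, H2B, H3 or H4 symbols above background on all 4 arrays, 34 were at least 2-fold lower and 2 higher in wild type (median -1.78), and 35 lower and 0 higher in knockout (median -1.83). H1f5, a linker histone gene, was -3.97 and -4.08, H2ac4 -3.53 and -3.85, and H3c11 -3.04 and -2.50. Histone paralogs are similar in sequence, and whether each probe reads its own gene alone was not tested. Between untreated knockout and wild type the same genes had a median of -0.04, with 2 lower.

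Some genes, also chosen after the values were seen, differed between genotypes in the same direction without and with LPS. The membrane protein genes Tmem176a and Tmem176b were 1.75 and 1.51 higher in knockout without LPS and 1.80 and 1.51 higher with LPS. Slc40a1, the gene of the iron exporter ferroportin, was 1.37 and 1.78 higher. Ms4a6b was -2.21 and -2.36, and its paralog Ms4a6c -1.94 and -1.08.

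Genes of chromosome 13 were slightly lower in knockout cells, a pattern found in a scan of 20 chromosomes, the autosomes and X: the median over 591 genes differed from that of the other chromosomes by -0.194 without LPS and -0.193 with LPS, and 78.8% and 70.9% of its genes lay below the median of the rest. A fault of 1 array is argued against by the weaker shift of -0.193, since the 2 comparisons share no array. Scaling acts on all genes of like signal alike, so normalization between arrays is argued against by the shift against genes of like signal on the other chromosomes: split in 3 by mean signal, every part was shifted, the weakest by -0.154. A difference in chromosome 13 copy number between the knockout and wild-type cells is a candidate explanation that needs every part to be shifted, as they were, the weakest by -0.154, but no DNA was measured. With the whole chromosome already seen to be shifted, shifted parts were likely in advance, so this result adds little for that explanation. The chromosome was also shifted in the wild-type LPS response, a comparison within 1 genotype, by -0.0967 (percentile 0 of matched gene sets), or -0.0556 without 34 histone genes. In the knockout response the shift was -0.0559 (percentile 7.75 of matched gene sets), or -0.0314 without them. With these histone genes left out, the shifts between knockout and wild type were -0.1987 without LPS and -0.1955 with LPS. Whether a change in copy number came with the knockout or with growth of the cell line was not tested.

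The LPS response of knockout cells passed the 2-fold rule for more genes, 4321 against 3330. The lowest ratio of the 2 counts over the scalings was 1.275. The scalings moved the all-gene medians of the wild-type and knockout responses nearly alike, to -0.174 and -0.184 with spike-in centring. They could therefore change the ratio little, and it does not decide whether normalization between arrays was a cause. Probes near background are argued against, since the ratio was 1.324 with only genes above background on both arrays, although it was 1.19 with no filter. The knockout array with LPS had the widest spread between replicate spots, an SD of 0.110 against 0.0520 to 0.0807 on the others. In data simulated with that spot noise, the call rule called 0 unchanged genes for the knockout response. This argues against noise between spots as the main source of the additional genes. Genes changed by slightly under 2-fold were not simulated, and error that replicate spots do not carry was not measured. A difference between single cultures other than genotype, such as a stronger exposure of 1 culture, cannot be told apart from genotype, since there was 1 LPS array per genotype. An effect of the knockout on the width of the LPS response was not tested and stays open.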
